A study of Mus musculus with 8 samples.

How the data were processed

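Poly(A) RNA of mouse CD11c positive bone marrow cells was sequenced in 8 libraries, 4 loaded with acLDL and 4 controls. Per the labels' protocols, RNA was extracted on RNeasy columns and libraries were made with the Lexogen QuantSeq V2 kit with dual indexes, which reads the 3' end of messages. The series' design text names the 5' end, and the kit in the extract protocol was taken as the better guide. Per the submitters' processing notes, bcl2fastq 2.20 and kallisto (no version given) were used with mm10, which is GRCm38. The annotation, the filters and the tool used for normalization are not given in the sources used here.

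The deposited table holds 1 normalized signal per gene symbol and library, in the authors' scale, for 11756 genes. It is named as raw counts, but the values are not whole and library totals are nearly equal. In each library, 11.0% to 12.5% of values are whole multiples of 1 step, at a tolerance of 0.01 steps, against 2% by chance. The steps run from 0.718 to 1.31 and have a geometric mean of 1, as dividing estimated counts by size factors would leave. Most values are not on a step, so reads could not be recovered. No value lies between 0 and 5, and the lowest gene total is 40.0, so low values had been set to 0 and low genes removed before deposit. A value listed at 0 may therefore stand for a low estimate. Dividing each total by its step gives an estimated depth of 3231070 to 5458180 reads per library. No counting interval was computed, because the values are not counts.

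The count model planned before the data were examined could not be used on this unit. In its place, genes with a value of at least 10 in at least 4 libraries (10091 genes) were tested with limma on log2(value + 5), with a variance trend and robust moderation, and with the group as the only term. The pseudocount of 5 is the floor of the table. Log2 fold changes are on this scale, as acLDL minus control, and understate changes of low genes. P-values were adjusted by Benjamini and Hochberg, with a threshold of 0.05. Gene lists, 33 in number, were fixed from general knowledge before the data were examined. Each had at least 3 tested genes and was tested with camera at a preset correlation of 0.01, two-sided. Camera with an estimated correlation and fry, which tests whether a list's genes move one way on balance, were run as well. Each list's mean per library was also compared by an exact permutation test over 70 assignments.

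Named genes follow a rule fixed before the data were examined. It takes up to 8 genes per direction that pass the threshold at a mean of at least 10 CPM without overlap between groups, and none qualified. It further takes from each list up to 3 members past the threshold or else the member with the smallest p, and 13 genes of the sorting marker, lipid handling and immune regulation. Some genes that the rule takes are not reported here. Genes named outside the rule are said to be so where they appear. Transcript lengths and coordinates came from GENCODE mouse release 21 (GRCm38), whose symbols matched 96.6% of the genes. The longest coding transcript of each symbol was used. Genes with near copies, such as ferritin, ribosomal protein, globin and MHC genes, are uncertain, because kallisto shares reads between similar transcripts.

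Alternatives planned from the start were median-of-ratios size factors, other filters, a replicate block, leaving out each library, leaving out mitochondrial and ribosomal protein genes, and the other list tests. Added after seeing the data were pseudocounts of 1 and 20, quantile normalization, the short-transcript index as a covariate, array weights, leaving out acLDL libraries 2 and 3 together, and restricting the genes to those above 0 in all libraries or to transcripts of 3000 nt or more.

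The fit was tested on simulated data for the comparison of acLDL with control, over 10091 genes in 20 draws. The draws kept the residual covariance between genes, and 200 genes were changed. Of genes changed by a log2 of 1, 13.95% were called, and of those changed by 2, 57.55%, with 5.61% false among calls. With no change, no draw called a gene. Camera at the preset correlation called at least 1 unchanged list in 8 of the 20 draws, and with an estimated correlation in 0. A shift of the sterol list by 1 was called in all 20 draws by both. The draws mixed the residuals of all libraries at random, so no library was set apart as some are in the data. There, another grouping of the libraries into 4 and 4 called 2888 genes. The sterol list, with a mean log2 fold change of -1.02, had camera's adjusted p = 0.10 with an estimated correlation. The simulated rates may therefore not hold for the data. Calculations used R 4.3.3, limma 3.58.1 and Python 3.11.15.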

Results

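RNA was measured in 8 libraries of mouse bone marrow cells that carry CD11c, an integrin found on dendritic cells and some macrophages. The cells came from C57BL/6 mice and had been isolated by flow cytometry. On culture day 6, cells in 4 libraries received acetylated low density lipoprotein (acLDL), a modified lipoprotein that scavenger receptors take up, and 4 libraries were controls. The exposure lasted 24 h. According to the series' design text, acLDL stands in for the lipid-rich surroundings of an atherosclerotic vessel. The deposited values were already normalized, with library totals from 3917430 to 4385050, and 10091 of the 11756 listed genes were tested. Nothing in the labels says that the 4 libraries of a group came from separate animals or cultures, so p-values measure the spread between these libraries, which may be technical.

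Genes of sterol synthesis and its control had the smallest p of all lists in the comparison of acLDL with control, which asks how CD11c positive cells respond to lipid loading. Of 22 measured members, 20 had a lower and 2 a higher mean log2 value with acLDL, and the list's median log2 fold change was -0.88, against -0.13 for all tested genes. The list as a set was lower in camera with the preset correlation (adjusted p = 3.2e-05 over 33 lists), and adjusted p = 0.10 with an estimated correlation. The mean of the list per library was -0.51 ± 0.39 (SD, n = 4) with acLDL and 0.51 ± 0.17 in controls, as log2 deviation from each gene's mean. The groups did not overlap, with a difference of -1.02 and p = 0.029 in a two-sided exact permutation test. This is the smallest p that 70 assignments allow, and it became 0.22 after Benjamini-Hochberg adjustment over the lists. The adjusted p could not have passed the threshold unless many lists had reached this smallest p.

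Hmgcs1, which encodes an early enzyme of the mevalonate pathway (chromosome 13, 119690379 to 119708260, plus strand, GRCm38), had the smallest p of the list. Its normalized value was 640.1 ± 76.0 (SD, n = 4) with acLDL and 1169.8 ± 182 in controls, a log2 fold change of -0.86 (SE 0.18) with limma's adjusted p = 0.298. Further members were chosen after their values were seen. Squalene epoxidase, Sqle (chromosome 15, 59315077 to 59331192, plus strand), averaged 32.3 ± 26.5 with acLDL and 115 ± 25.8 in controls. Sc5d averaged 105 ± 23.1 and 199 ± 42.2. Srebf2, the transcription factor that drives this pathway, averaged 104 ± 62.6 and 213 ± 29.1, with acLDL library 1 at 192 and control library 1 at 193. With an index of short transcripts per library as a covariate, described below, the log2 fold change went from -1.16 to -0.48 for Srebf2, from -1.88 to -1.10 for Sqle and from -0.89 to -0.75 for Sc5d, and from -0.86 to -0.93 for Hmgcs1. Tm7sf2 and Acat2 were the members with a higher mean. No member passed limma's threshold over all genes, and 7 passed when adjusted over the list alone, all of them lower, among them Hmgcs1, Sqle, Sc5d, Fdps, Ebp and Srebf2. Camera's call at the preset correlation held when each library was left out in turn, with medians from -1.02 to -0.82 when each was left out.

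**Figure D1:**
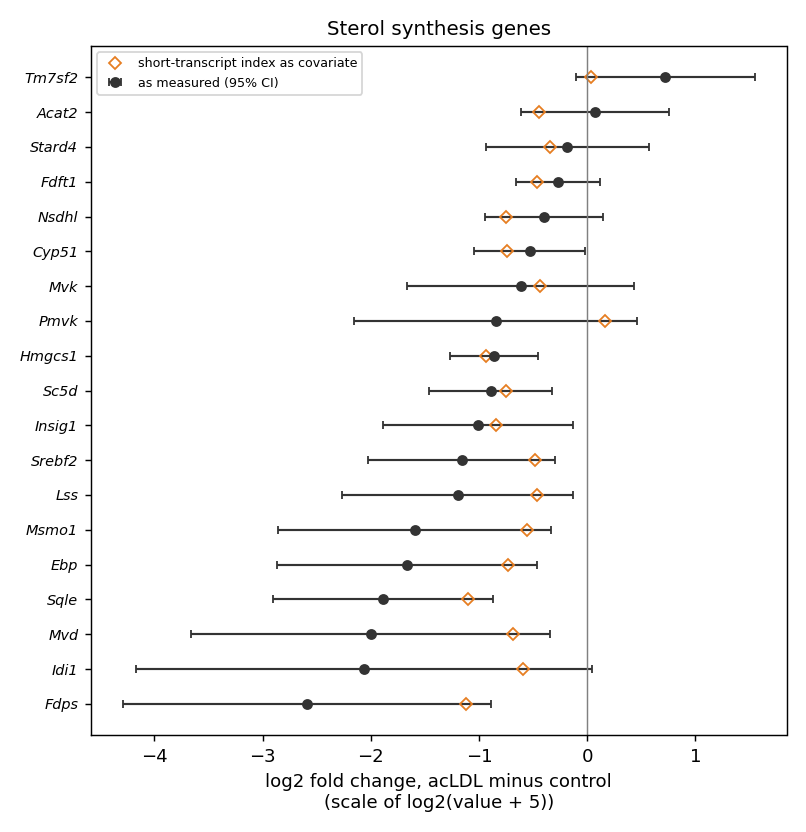
Log2 fold change of 19 of the 22 tested sterol synthesis genes between acLDL and control libraries (n = 4 each). Filled circles give limma's value with its 95% confidence interval and open diamonds the value with the short-transcript index of each library as a covariate. Of the filled circles, 17 lie below 0, and the median of the whole list is -0.88.

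No list of genes that take up, store or export cholesterol passed the threshold. Of 16 tested targets of the liver X receptors (LXR), the nuclear receptors that respond to oxysterols, 5 had a higher and 11 a lower mean, with a median of -0.23 and camera's adjusted p = 0.64. The cholesterol exporter Abca1 averaged 91.1 ± 106 (SD, n = 4) with acLDL and 183 ± 85.9 in controls, and Abcg1 282 ± 252 and 589 ± 96.3. Plin2, which coats lipid droplets, averaged 709 ± 209 with acLDL and 410.2 ± 66.5 in controls (log2 fold change 0.75, SE 0.25, limma's adjusted p = 0.298). Of 12 genes for uptake of modified lipoproteins, 5 had a higher and 7 a lower mean (median -0.06, adjusted p = 0.90). The scavenger receptor Msr1 averaged 1627 ± 228 and 1228 ± 81.2, Cd36 4457 ± 427 and 4608 ± 322, and Scarb2 1489 ± 499 and 823 ± 166. Of 17 genes for cholesterol esterification and lipid droplets, 7 had a higher and 10 a lower mean (median -0.13, adjusted p = 0.90). Among them, Lipa, the acid lipase of lysosomes, averaged 977 ± 144 and 1573 ± 158. The fatty acid synthesis list, with 13 genes tested, had a median of -0.37 (adjusted p = 0.48). The list of PPAR targets and fatty acid oxidation, with 17 genes, had a median of -0.05 (adjusted p = 0.99), and its member Fabp4 averaged 752 ± 371 with acLDL and 1566 ± 89.4 in controls. None of these genes passed limma's threshold. With the short-transcript covariate, the log2 fold change went from -1.35 to -0.07 for Abca1, from -1.44 to -0.27 for Abcg1, from 0.75 to 0.33 for Plin2, from 0.81 to 0.32 for Scarb2 and from -1.18 to -0.60 for Fabp4. It moved less for Msr1, from 0.40 to 0.39, and for Lipa, from -0.69 to -0.56.

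Interferon-stimulated genes were lower as a set, with 22 of 31 measured members lower with acLDL and a median log2 fold change of -0.70. Camera's adjusted p was 0.019 with the preset correlation, and adjusted p = 0.63 with an estimated correlation. Gbp7, a guanylate-binding protein, averaged 136 ± 30.5 (SD, n = 4) with acLDL and 267 ± 61.7 in controls (limma's adjusted p = 0.298). Without acLDL library 1 the call ended (adjusted p = 0.066). Camera called 4 more lists, all lower with acLDL at the preset correlation, each with adjusted p = 0.74 with an estimated correlation. NF-kB targets had 19 of 23 members lower (median -1.10, adjusted p = 0.019), among them the cytokine gene Il1b at 36.9 ± 26.3 and 120.3 ± 42.0. This call ended without control library 4 (adjusted p = 0.051). Immediate-early and heat shock genes had 18 of 22 members lower (median -0.82, adjusted p = 0.016), among them the transcription factor Klf4 at 111 ± 18.4 and 224 ± 41.0. MHC class I presentation genes had 12 of 14 members lower (median -1.50, adjusted p = 0.019), among them Tapbp, which loads peptides, at 46.5 ± 42.5 and 108 ± 24.8. Granulocyte markers had 16 of 19 members lower (median -1.66, adjusted p = 0.019), among them the granule protein gene Ngp at 199.7 ± 320.4 and 630.5 ± 345. Over all genes no member of these 5 lists passed, and adjusted over the list alone 1 did, Klf4. In all 5 lists acLDL library 1 lay within the range of the controls, and acLDL libraries 2, 3 and 4 lay below every control. With the short-transcript covariate, the interferon list was called at the preset correlation (adjusted p = 0.0018, median -0.22) but not with an estimated correlation (adjusted p = 0.22), and the other 4 were called with neither. With it the log2 fold change went from -1.41 to -0.43 for Tapbp and from -3.45 to -0.38 for Ngp. For Il1b it went from -1.69 to -1.23, for Gbp7 from -0.94 to -0.82 and for Klf4 from -0.98 to -1.18. Under fry none of these 5 passed. In camera without acLDL libraries 2 and 3 the NF-kB (adjusted p = 0.17), MHC class I (0.17) and granulocyte (0.23) calls ended. The granulocyte call also ended with a filter at 10 CPM (0.11) and among genes above 0 in all libraries (0.31). Among transcripts of 3000 nt or more, the NF-kB (0.25), immediate-early (0.13) and granulocyte (0.68) calls ended, and the interferon call held (0.0082).

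**Figure D2:**
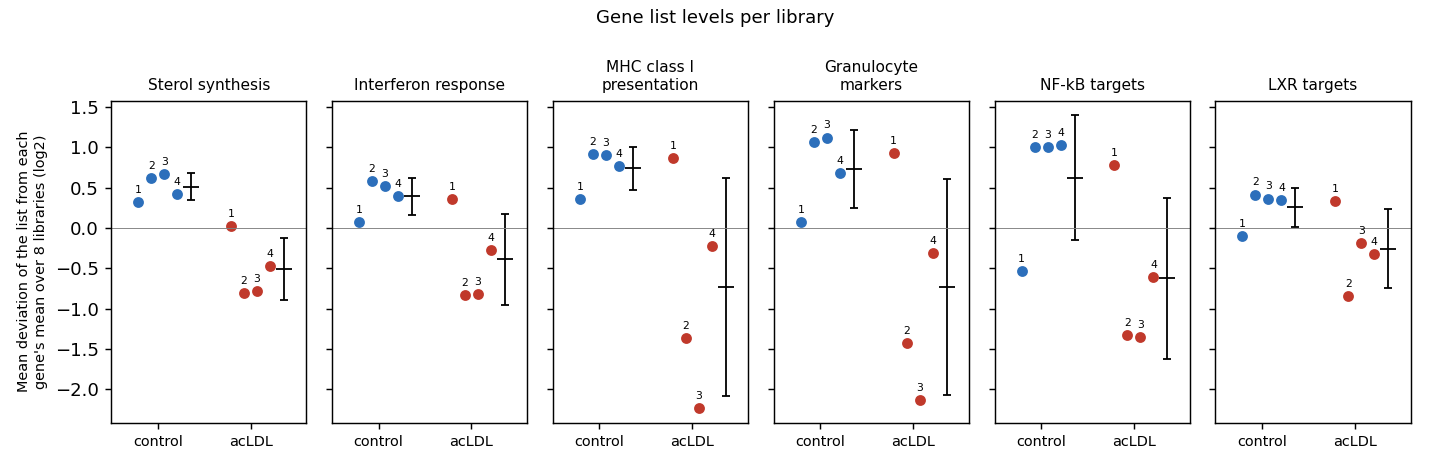
Mean log2 deviation of 6 gene lists in each of the 8 libraries from each gene's mean over all libraries. Points are libraries, numbered by replicate, and the bars beside them give the mean ± SD of each group (n = 4). In the sterol list the acLDL libraries lie between -0.81 and 0.02 and the controls between 0.32 and 0.67, whereas in the granulocyte list acLDL library 1, at 0.93, lies within the range of the controls.

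Genes of dendritic cell maturation, antigen display to helper T cells and tolerance showed no set-wide difference past the threshold. Of 18 maturation genes, 13 were lower (median -1.20, adjusted p = 0.36), while the chemokine gene Ccl22 averaged 6643 ± 529 (SD, n = 4) with acLDL and 4950.4 ± 421 in controls. The costimulatory ligand gene Cd86 averaged 138 ± 23.6 with acLDL and 87.2 ± 10.1 in controls, with no overlap between the groups (log2 fold change 0.62, SE 0.23, limma's adjusted p = 0.298). With the short-transcript covariate the log2 fold change was 0.70 for Cd86, and it went from 0.42 to 0.46 for Ccl22. Cd80 averaged 47.3 ± 27.4 and 30.9 ± 16.0, and Cd40 38.7 ± 2.13 and 32.1 ± 7.84. Of 21 tolerance genes tested, 10 were higher and 11 lower (median -0.11, adjusted p = 0.90). Socs2, a suppressor of cytokine signalling, averaged 1638 ± 365 with acLDL and 992 ± 213 in controls, and its log2 fold change of 0.72 went to 0.38 with the short-transcript covariate. Cd274, which encodes the inhibitory ligand PD-L1, averaged 699.7 ± 346 and 397 ± 133, and its log2 fold change of 0.71 turned to -0.15 with this covariate. With that covariate the median of the maturation list turned to 0.22 and that of the MHC class II list to 0.03. Il10 and Tgfb1 are not among the genes of the table used here. Of 12 MHC class II genes, 8 were lower (median -1.55, adjusted p = 0.36), and members went apart. H2-Eb1 averaged 34549.8 ± 9348 with acLDL and 22132 ± 3387 in controls, and its log2 fold change of 0.61 went to 0.19 with the covariate. H2-Aa, chosen after its values were seen, ranged from 29.4 to 6232 with acLDL and from 1610.4 to 6463 in controls. Of 20 chemokines and their receptors, 13 were lower (median -0.69, adjusted p = 0.48). Camera called this list after quantile normalization (adjusted p = 0.040), and not with an estimated correlation (0.74). Among the lower members was Ccr2, the receptor that guides monocytes, at 1088 ± 416 and 1983 ± 111 (log2 fold change -0.94, and -0.46 with the covariate).

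Itgax, the gene of the sorting marker CD11c, averaged 60.4 ± 87.5 (SD, n = 4) with acLDL and 158 ± 51.7 in controls. It was listed between 0 and 189 with acLDL and between 81.5 and 195 in controls. Its log2 fold change was -2.42 (SE 0.98), and -0.22 with the short-transcript covariate. Of the marker lists other than granulocytes, none passed the threshold. The median log2 fold change was -1.15 over 19 macrophage markers and -1.19 over 10 monocyte markers (adjusted p = 0.36 for both). It was -0.90 over 8 markers of conventional dendritic cells of type 2 (adjusted p = 0.46), -0.15 over 9 of type 1 (adjusted p = 0.90) and -0.19 over 7 general dendritic cell markers (adjusted p = 0.49). Plasmacytoid dendritic cell markers had a median of -0.28 over 5 genes (adjusted p = 0.66) and mast cell and basophil markers -0.18 over 5 genes (adjusted p = 0.90). Medians were positive for 4 lymphocyte markers, at 0.73 (adjusted p = 0.46), and for 7 stromal and osteoclast markers, at 0.49 (adjusted p = 0.48), where the mean was -0.12. The 4 erythroid and megakaryocyte markers were all lower (median -2.57, adjusted p = 0.052), with the globin gene Hbb-bs at 97.0 ± 62.7 and 701 ± 569. Hbb-bs had a log2 fold change of -2.52, and -2.94 with the short-transcript covariate. It shares most of its sequence with its neighbour Hbb-bt, so its level is uncertain. The erythroid list was called under some alternatives, among them quantile normalization (adjusted p = 0.0080) and the replicate block (0.038), and not with an estimated correlation (0.74). Camera also called the macrophage list after quantile normalization (adjusted p = 0.015), and not with an estimated correlation (0.74). With the short-transcript covariate the medians went to -0.08 for erythroid, 0.06 for macrophage, -0.19 for monocyte and 0.03 for type 2 dendritic cell markers.

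The remaining metabolic, stress and housekeeping lists did not pass the threshold. The median was -1.32 over 30 oxidative phosphorylation genes and -0.32 over 37 lysosomal genes (adjusted p = 0.22 for both). It was -1.12 over 40 ribosomal protein genes (adjusted p = 0.36) and -0.55 over 12 genes of the mitochondrial genome (adjusted p = 0.21). Camera called the mitochondrial list under some alternatives, among them without control library 1 (adjusted p = 0.014) and quantile normalization (0.0019). It did not with an estimated correlation (0.74). Quantile normalization also brought calls for oxidative phosphorylation (0.0033), lysosomal (0.0069) and ribosomal protein genes (0.00088). The targets of NRF2, with 23 genes, had a median of -0.46 (adjusted p = 0.36), and the unfolded protein response list, with 21, a median of -0.42 (adjusted p = 0.46). With the short-transcript covariate the medians turned to 0.10 for oxidative phosphorylation, 0.13 for ribosomal proteins and 0.12 for the unfolded protein response. Of the 31 lists with a negative median, 14 had a positive one with this covariate. Gpx4, which detoxifies lipid peroxides, averaged 71.2 ± 94.6 (SD, n = 4) with acLDL and 251 ± 52.0 in controls. Its value in acLDL library 1, 207, lay within the range of the controls, and its log2 fold change went from -2.75 to -0.83 with the covariate. The medians of 35 cell cycle genes (-0.15, adjusted p = 0.48) and 22 genes of glycolysis and hypoxia (-0.01, adjusted p = 0.81) lay close to that of all genes. Against the other genes, camera placed these lists slightly higher although their medians and means were negative, and likewise the general dendritic cell, tolerance, modified lipoprotein and PPAR lists.

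No single gene passed limma's threshold, in either direction, with the smallest adjusted p at 0.298. At an unadjusted p under 0.05 there were 1650 genes, 749 higher and 901 lower, against 505 by chance. With the short-transcript covariate there were 467, and without acLDL libraries 2 and 3 there were 305, both below the number by chance. The index behind the covariate was lower in acLDL libraries 2, 3 and 4 than in every control. Adjusting for it may therefore also remove an effect of acLDL. The second count compared fewer libraries and kept acLDL library 1, which was closest to control library 3. Neither count shows that no gene changed. Values of the groups did not overlap for 569 genes, or 5.64%, against 2.86% by chance. Among the genes with the smallest p, chosen after their values were seen, were an 18S ribosomal RNA repeat, Rn18s-rs5, and the glutamate transporter gene Slc1a7. Rn18s-rs5 ranged from 19306 to 34320 with acLDL and from 60775 to 203753 in controls, where it took up to 4.91% of a library's total. Copies of this repeat cannot be told apart. Its log2 fold change of -2.00 went to -2.30 with the short-transcript covariate. Whether RNA quality or preparation differed between the groups was not tested. Slc1a7 ranged from 18.3 to 30.9 with acLDL and was listed at 0 in the 4 controls. The count of 0 rested on acLDL library 1: without it 2190 genes passed, 735 higher and 1455 lower. The longest transcript was under 1500 nt in 36.7% of these lower genes and 13.9% of the higher ones, against 16.1% of all tested. The median log2 fold change of all tested genes depended on the scaling, at -0.13 as deposited and 0.15 after quantile normalization.

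The main difference between libraries followed transcript length more than the groups. The first principal component carried 62.6% of the variance, with acLDL libraries 1 to 4 at -66.6, 95.6, 129 and 32.2 and control libraries 1 to 4 at 9.22, -75.3, -67.3 and -56.4. By Spearman correlation over genes, acLDL library 1 was closest to control library 3 (0.94), and control library 1 was closest to acLDL library 4 (0.88). Genes whose longest coding transcript is under 1000 nt were low in acLDL libraries 2 and 3. A short-transcript index was taken for each library, as the median log2 deviation of coding genes under 1000 nt minus that of genes of 3000 nt or more. It was 1.18, -1.43, -2.41 and -0.24 in acLDL libraries 1 to 4 and 0.23, 1.06, 1.15 and 0.73 in controls. The groups averaged -0.73 ± 1.55 (SD, n = 4) and 0.79 ± 0.41, with p = 0.14 in a two-sided exact permutation test. Some abundant short transcripts showed it and others did not, here chosen after their values were seen. The ferritin light chain gene Ftl1 was at 34936, 1435, 339 and 9295 in the acLDL libraries and the calprotectin gene S100a8 at 6019, 303, 36.3 and 1695. In contrast, Fabp5, with a transcript of 987 nt, averaged 77574 ± 16756 with acLDL and 76520 ± 7237 in controls, and Lgals1, with one of 800 nt, had a log2 fold change of 0.31. Some longer genes went down as well, such as Psap, a precursor of lysosomal saposins with a transcript of 2657 nt, at 473 in acLDL library 3 and 50746 in acLDL library 1. So did genes with far longer transcripts: in acLDL libraries 1 to 4, Abca1 (10262 nt) was at 248, 28.3, 32.5 and 55.1, Abcg1 (5832 nt) at 641, 122, 94.0 and 271, and Itgax (4046 nt) at 189, 10.004, 0 and 42.7. In the classes from 3000 nt on, library medians ran from -0.034 to 0.14.

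**Figure D3:**
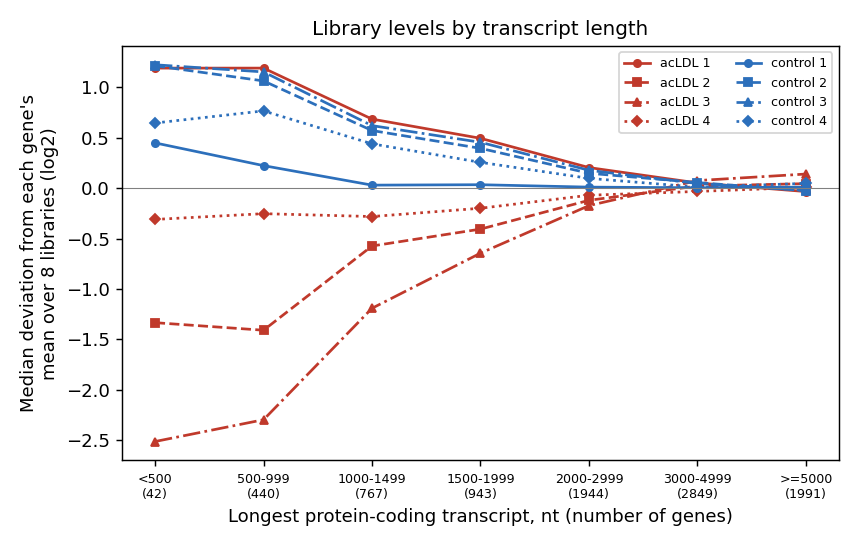
Median log2 deviation from each gene's mean over 8 libraries, by length class of the longest coding transcript, with the number of genes in each class in parentheses. Lines are libraries, red for acLDL and blue for control. In the class from 500 nt to under 1000 nt, acLDL libraries 2 and 3 lie at -1.41 and -2.30 and acLDL library 1 at 1.19, and from 3000 nt on the lines meet near 0.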

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

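Of the tests in this part, those on transcript length, depth, exchanged labels and granulocyte markers, the short-transcript covariate, and the splits for the number of genes and for the sterol list as deposited were chosen after the result was seen.

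Within 156 groups of 4 libraries, 14 held a library far from the other 3, where chance gives about 1 in 20. All 14 were acLDL library 1 or control library 1. In acLDL library 1, Il1b was at 75.7, Hmgb2 at 188, Ngp at 674, Elovl5 at 32.8 and Abca1 at 248. The other acLDL libraries reached at most 27.4, 35.3, 113, 0 and 55.1. The mean deviation of the cholesterol esterification list was 0.25 there. In control library 1, Hmgcs1 was at 1442, and 7 lists lay below the other controls. Their mean deviations were -0.10 for LXR targets, -0.097 for PPAR targets, -0.53 for NF-kB targets, -0.25 for the unfolded protein response, -0.24 for immediate-early genes, -0.69 for type 2 dendritic cell markers and 0.035 for macrophage markers.

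The first principal component followed the groups only in part. It averaged 47.4 ± 85.9 (SD, n = 4) with acLDL and -47.4 ± 38.6 in controls, with p = 0.086 in a two-sided exact permutation test. The labelled grouping called 0 genes, which all 35 splits of the libraries into groups of 4 reach whatever the data, so this count of splits says nothing on chance. The highest other split gave 2888, which points to a structure of the samples. Fewer reads in some libraries stay open. The Spearman correlation of the component with estimated depth was 0.29 (exact permutation p = 0.50), Pearson's r was -0.029 (p = 0.94), and without acLDL libraries 2 and 3 r was 0.69. Of the libraries farthest along it, acLDL library 2 had the lowest depth (3231070) and acLDL library 3 did not (4330580). This met the criterion written for excluding depth, which was too lax, since it rests on a missed threshold and 1 library. A loss of short transcripts in some libraries remains open. It should also show among the 12 genes of the mitochondrial genome, and the length slopes over mitochondrial and nuclear genes had r = 0.66 (exact permutation p = 0.076, 0.15 adjusted over both relations) and Spearman's 0.57 (p = 0.15). Without acLDL libraries 2 and 3, r was 0.34, so the relation rests on them. Not every short transcript was low, as Fabp5 (987 nt), with a log2 fold change of 0.00052, was not, and some long ones were low in acLDL libraries 2 and 3, such as Abca1 (10262 nt) and Abcg1 (5832 nt). Length alone therefore does not describe the component. Exchanged labels of acLDL library 1 and control library 1 cannot be told apart from a difference in preparation. The exchanged grouping is the split with 2888 genes, but the exchange was proposed from the component itself, so this count is no evidence for it. The same holds in part with the short-transcript index as a covariate, where it gave 1192 genes at an unadjusted p under 0.05 against 467 as labelled. The sterol list of acLDL library 1 lay below the lowest control (difference -0.30, control SD 0.17), but reading labels from it assumes that acLDL lowers the list. The sterol result depends on the labels: without the covariate camera's p was 9.7e-07 as labelled and 0.081 after the exchange. With the covariate it was 4.7e-12 and 0.99. After the exchange the index separates the groups completely, so the covariate takes up much of the group's effect and the 0.99 says little. The mean deviation of the further SREBP2 targets was -0.41 in acLDL library 1 and 0.57 in control library 1, under the same assumption.

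The granulocyte list was lower with acLDL. Fewer granulocytes would lower short and long markers alike only if both were equally specific to granulocytes, which was not tested. The median log2 fold change was -0.48 over 8 markers of 2000 nt or more and -2.09 over 11 shorter ones. The difference was 1.61 (exact permutation p = 0.00074 across genes, which are not independent replicates), and it cannot decide whether granulocytes were fewer. With the short-transcript index as a covariate the list's median went from -1.66 (SD over members 1.11) to -0.028 (SD 0.44), and the call ended because the estimate itself moved to 0. The index is built from short genes of these same libraries, and the list's median transcript length is 1025 nt. Such a list would move towards 0 whatever lowered it, so the covariate cannot decide the cause. A loss of short transcripts remains possible for this list. How far sorting for CD11c removed granulocytes was not tested, and Ngp ranged from 249 to 971 in controls.

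The sterol list was lower with acLDL. With the same covariate its median went from -0.88 (SD over members 0.83) to -0.67 (SD 0.37). Camera's adjusted p was then 1.6e-10 at the preset correlation and 0.021 with an estimated one. The trend that the index describes therefore does not account for all of the difference. The list's median transcript length is 2892.5 nt, and some long genes were low in the same acLDL libraries as the short ones. Other differences between the libraries are thus not excluded. Chance could not be excluded as deposited, since 2 of the 35 splits gave as small a p (-log10 p 6.01 as labelled, 6.05 in the highest other split). With the covariate 1 of 35 did, the labelled one (11.3, against 6.81 for the highest other). This excludes chance at the 0.05 level only for this list taken alone. It does not cover the list's choice as the smallest p of 33 lists, or a covariate chosen after the result was seen. Without the covariate, the exact permutation p adjusted over the lists was 0.22. With 70 assignments that p could not pass unless many lists reached the smallest value, so it cannot decide the choice. A response to the sterol load, which the design implies, is a hypothesis found and tested on the same data.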

How the results depend on the processing

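The pseudocounts, quantile normalization, the short-transcript covariate, array weights, the exclusion of acLDL libraries 2 and 3 together and the limits to genes above 0 or to transcripts of 3000 nt or more were chosen after seeing the data. No count model, neither DESeq2, limma-voom nor the older quasi-likelihood fit, was run, because the values are not counts. The count of 0 genes stayed 0 under 18 of 21 alternatives; it was 1 after quantile normalization and 1957 with array weights, which gave acLDL library 1 the lowest weight, 0.34. Leaving out each library gave 0 to 2190 genes, the 2190 without acLDL library 1, of which 1579 were shared with the weighted fit. The 6 lists became 13 after quantile normalization, 3 with the short-transcript covariate, 2 among transcripts of 3000 nt or more, 1 with fry (sterol, adjusted p = 0.0081), 0 with an estimated correlation, and 1 with both covariate and estimated correlation (sterol, adjusted p = 0.021); leaving out each library gave 5 to 7. Without acLDL libraries 2 and 3 together, 0 genes and 4 lists passed. The cause of these shifts was not tested. The sterol median of -0.88 was -1.02 to -0.82 without single libraries and -0.66 without acLDL libraries 2 and 3; its adjusted p reached 0.10 only with an estimated correlation, and over the other 23 alternatives ran from 1.6e-10 to 0.021. The replicate block gave 0 genes, 7 lists and a sterol median of -0.88. Same-numbered libraries did not deviate together over all genes (correlations -0.55, -0.21, -0.28 and 0.034). The first principal component, with 62.6% of the variance, weighs on these correlations. They therefore cannot decide whether a shared number means a shared origin. Of 827 values of named genes under alternatives, 763 kept direction and call, 61 came to pass the threshold (29 without acLDL library 1, 32 with array weights) and 3 changed sign: Cd274 to -0.15 and Cd36 to 0.050 with the covariate, and Cd36 to 0.056 without acLDL libraries 2 and 3. Estimated depth, 3231070 to 5458180 reads, limits genes near the floor of 5.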

Other observations

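The tests on LXR targets and all values with the short-transcript covariate were chosen after the result was seen. The tests on further SREBP2 targets and on the number of lists over splits were written before it.

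Of the 14 lists whose negative median turned positive with the short-transcript covariate, the cell cycle list was the only one called. With this covariate, the 35 genes had a median log2 fold change of 0.29 and camera's adjusted p = 0.012 at the preset correlation, and adjusted p = 0.21 with an estimated correlation. Without the covariate the median was -0.15 and members went both ways. Among members chosen after their values were seen, the cyclin gene Ccna2 had a log2 fold change of 0.88 (SE 0.28) without the covariate. The mitotic kinase gene Aurka had one of 0.72 (SE 0.27), and neither passed limma's threshold (adjusted p = 0.298). With the covariate Ccna2 went to 0.71 and Aurka to 0.57, so they did not follow the rise of the list's median. Hmgb2, at -2.38 (SE 0.69) and at -0.99 with the covariate, went against them.

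If the sterol list was lower because SREBP2, a transcription factor whose activity depends on cell sterol, was less active, its targets outside the list should be lower as well. Of 7 such genes 5 were tested, and 5 of 5 had a negative log2 fold change. The median over all tested genes was negative too, at -0.13. Their mean deviation per library was -0.36 ± 0.31 (SD, n = 4) with acLDL and 0.36 ± 0.17 in controls, with a two-sided exact permutation p = 0.029, the smallest that 70 assignments allow. Tmem97 averaged 18.2 ± 2.80 with acLDL and 41.1 ± 16.1 in controls, and Acss2 15.9 ± 21.1 and 67.4 ± 36.6. The other 3, Mmab, Rdh11 and Cyb5b, had log2 fold changes of -0.06, -0.16 and -0.13, near the median of all tested genes. The result therefore rests mostly on Tmem97 and Acss2, both low, and Acss2 was listed at 0 in acLDL libraries 2 and 3. A lower activity of SREBP2 may account for both lists, but these low genes cannot decide it. A rise in LXR targets, which sterol loading could also bring, was not seen: their median was -0.23 and camera's adjusted p = 0.64. With the short-transcript covariate the median was again -0.23 (camera's adjusted p = 0.45), so no rise was seen with it either. The index describes the differences between these libraries only in part, so the question stays open.

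As many lists as the 6 called were called in 2 of the 35 splits of the libraries, and the highest other split called 7, so chance could not be excluded for the number of lists.

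In 20 genes the values were above 0 in all 4 libraries of one group and listed at 0 in all 4 of the other, 11 of them with acLDL only and 9 in controls only. As many were found in 8 of the 35 splits, with up to 206 in another split. They include the chemokine gene Ccl24, at 6.91 to 34.9 with acLDL, and Tnfsf4, which encodes the costimulatory ligand OX40L, at 9.38 to 26.8 in controls. Both genes lie near the floor of 5, and neither entered the gene test.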
